A study of Gossypium hirsutum with 24 samples.

How the data were processed

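RNA from 24 cotton samples was labelled with a 3′ in vitro transcription kit and hybridised to Affymetrix Cotton Genome arrays, per the labels' protocols. The deposited values are on the log2 scale and were made by the authors with GCRMA, per the submitters' processing notes; its version and options are not given in the sources used here. GCRMA corrects the background from probe sequence, normalizes between arrays and summarises probes into probe sets. Of all values, 26.2% stood at the lowest value of the table, so differences from that level are compressed. No scanner files were used here, and no further normalization was applied. All 24 value columns were matched to samples by their labels.

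The table held 24132 probe sets, and the 155 control probe sets were left out of the tests. The labels state that targets for the reporter and tag controls were not added, so the 95th percentile of these 69 probe sets over all arrays, 2.23, was taken as background. A reporter control with signal on every array, averaging 14.2, was kept among them. A probe set was tested where at least 3 arrays exceeded background, which left 17666 of 23977. Where a group was at or below background on all 3 arrays, the fold is a lower bound, computed from the brighter group's mean against the background level or the dim group's own values where these were higher. Of the tested probe sets, 5551 held exactly the same value on at least 3 arrays, above background in 2952 and with some array lower still in 3866. A group with such a value on all its arrays has no measured spread, so a difference from it is given as approximate; whether the value stands for no signal is not given in the sources used here.

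Samples were grouped by tissue and bud size as labelled. A linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, and its moderated two-sided test was adjusted by Benjamini-Hochberg within each comparison. A call needed an adjusted p under 0.05 and an absolute log2 difference of at least 1. The comparisons, tests, thresholds, filter, gene lists and all alternatives except spike-in scaling, the exclusion of 4 or 5 arrays and a poly-A spike-in covariate were fixed before the data were examined. The series text calls the replicates biological and does not say from which plants they came. No scan date or slide was given in the table used, so such batches were not examined.

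On simulated data made from the real group means and variances, with 200 of 17666 probe sets changed in the 7 mm comparison of anthers and buds, 89.4% of changes of 1.5 log2, 91.0% of changes of 2 and 98.5% of changes of 3 were called, with 1 false call. The changed probe sets were drawn from those with every group mean over 2 log2 units above background. Noise was normal, with 1 variance per probe set and no lower limit. These shares and the false call therefore do not carry over to probe sets near the lower limit or with uneven spread. Unchanged groups, with the same mean in all groups, were simulated 20 times for the sets.

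The platform annotation listed genes for 743 probe sets, 697 with a single symbol and 46 with several; the others are unnamed here. All 697 matched the gene table of assembly Gossypium_hirsutum_v2.1 and all were locus numbers. No coordinates are printed because the build behind the platform annotation is not given in the sources used here. The 26 gene lists, which search product names, found 0 members, so no set test was run. The rule fixed beforehand named, where few genes have descriptive names, the 2 probe sets that rose most and the 2 that fell most per comparison, among calls whose groups did not overlap on any array (chance alone separates groups of 3 in 10% of cases). A rule added after the annotation was seen, and before the comparisons were computed, also named the 5 locus genes that rose most and the 5 that fell most in the comparisons of anthers with buds and the anther steps, 2 and 2 in the others, and 4 in each set. Probe sets without a symbol are given by rank, not by identifier, and not all of them are given. That choice was made after their values were seen. Probe sets ending in s_at or x_at can bind transcripts of several related genes, and 8481 of those tested have such names.

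Alternatives covered the filter, a floor at background, quantile normalization, median centring, the variance prior, array weights, the arrays in the fit, the thresholds, probe set types, the replicate number as a block and each array of the compared groups left out in turn. The array weights stopped before full convergence. Figures were drawn with matplotlib 3.10.9.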

Results

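Transcript levels were measured on 24 Affymetrix Cotton Genome arrays, 1 per RNA sample of upland cotton (Gossypium hirsutum). Anthers, the pollen-forming organs of the flower, were dissected from flower buds of 5, 7 and 8 mm, and the rest of each bud was kept as a separate sample. Young leaf and seedlings served as vegetative tissues. Each of the 8 groups had 3 arrays, described in the series as biological replicates. The series covers stages before, during and after meiosis, which its authors matched to the tapetum, the nutritive cell layer of the anther. The labels do not state which bud size stands for which stage, so groups are named by size. Between 64.5% and 67.1% of the probe sets that were not controls lay above background on each array, and the number of arrays limits the precision.

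Of 17666 tested probe sets, 634 had a single gene symbol. Every symbol was a locus number with no product name, so genes are given by locus number, without a function. Probe sets without a symbol are given by their rank. None of the 26 gene lists fixed beforehand found a member, so no pathway or cell type is described.

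The arrays separated by tissue, and those of anthers, but not those of buds, also by bud size. The first principal component held 46.4% of the variance and set leaf and seedling apart from anthers, with buds between them. The next held 24.8% and set buds without anthers apart from the other tissues. Across probe sets, anther and bud arrays of the same size correlated with a median r of 0.89, against 0.95 between anthers of different sizes and 0.98 between buds of different sizes. Within the anther groups of 5, 7 and 8 mm the median r was 0.976, 0.990 and 0.985. Within the bud groups it was 0.960, 0.957 and 0.984, so buds of different sizes were about as alike as buds of the same size. Probe sets are not independent replicates, so these values only describe the arrays. The lowest r within a group was 0.948, in 7 mm buds, and no 2 arrays held identical values.

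**Figure D1:**
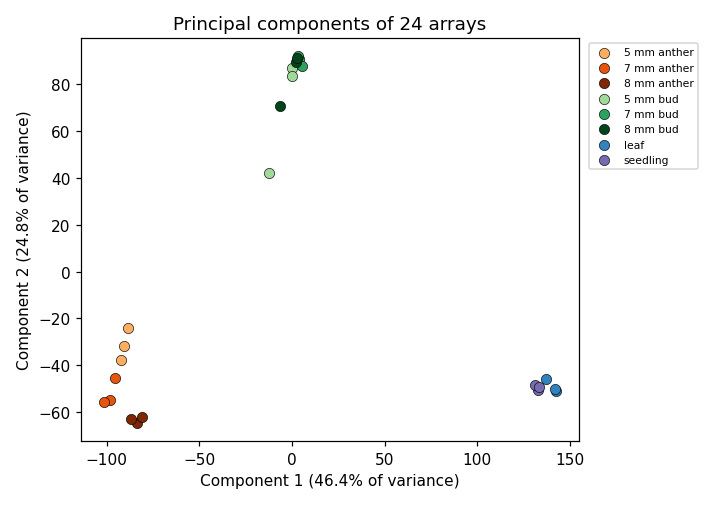
Principal components of the 24 arrays over 17666 tested probe sets; each point is 1 array, coloured by group, with component 1 (46.4% of the variance) and component 2 (24.8%) on the axes. Anthers, buds without anthers, and leaf with seedling lie apart, and 5 mm bud replicate 2 lies nearest to the anthers among the bud arrays.

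The first question was which transcripts distinguish anthers from the rest of the bud. In 5 mm buds, 1775 probe sets were higher and 2112 lower in anthers. Among genes with a locus number, LOC107933034 rose to 7.92 ± 2.14 (SD, n = 3) in anthers from 3.57 ± 0.62 in buds without anthers, a log2 difference of 4.35 (SE 0.68, adjusted p = 4.62e-05). LOC107956851 rose by about 4.28, from 3.76 on all 3 bud arrays, a value that this probe set holds on 7 of the 24 arrays and that gives no exact size. LOC107961466 rose by 2.99, LOC107956913 by 2.78 and LOC107925198 by 2.73. LOC107933034 and LOC107956851 stood at 3.11 and 2.99 without 5 mm anther replicate 1 and at 5.00 and 5.06 without 5 mm anther replicate 4, and both lost their calls in a fit of these 6 arrays alone. Falls were larger, with log2 differences of -7.09 for LOC107914060, -7.04 for LOC107913771, -6.64 for LOC107958067 and -6.21 for LOC107905899. LOC107889256 was at background on all 3 anther arrays and at least 58.8-fold lower there. Probe sets without a symbol moved further still, the highest ranked rising by 6.69 (SE 0.33, adjusted p = 1.65e-11; 7.31 without 5 mm anther replicate 1) and the lowest ranked being at least 891-fold lower.

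In 7 mm buds, 2306 probe sets were higher and 2629 lower in anthers. LOC107923176 rose to 9.45 ± 0.08 (SD, n = 3) in anthers from 2.90 ± 0.26 in buds, a log2 difference of 6.55 (SE 0.85, adjusted p = 4.15e-06). LOC107956851 rose by 6.49, LOC107949717 by 5.50, LOC107959059 by 5.40 and LOC107933034 by 5.05. The largest falls of locus genes were -7.80 for LOC107914060, -7.46 for LOC107958067, -7.13 for LOC107915836, -7.01 for LOC107892108 and -6.98 for LOC107913771. The highest ranked probe set without a symbol was at background on all 7 mm bud arrays and at least 465.9-fold higher in anthers (adjusted p = 4.24e-11), and the lowest ranked fell by 10.32.

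In 8 mm buds, 1955 probe sets were higher and 2403 lower in anthers. LOC107933034 rose by 4.35 (SE 0.68, adjusted p = 3.91e-05), from 5.25 ± 0.13 (SD, n = 3) in buds to 9.60 ± 1.07 in anthers, and stood at 3.73 without 8 mm anther replicate 7. LOC107923176 rose by 4.00, to 7.03 ± 2.84 in anthers. Its difference was 2.80 without 8 mm anther replicate 1 and 5.57 without replicate 7, and it lost its call in a fit of these 6 arrays alone. LOC107961466 rose by 3.78 and LOC107939787 by 3.42, and LOC107930564 was at background on the bud arrays and at least 16.1-fold higher in anthers. The largest falls were -8.34 for LOC107913771 (-9.04 without 8 mm anther replicate 7), -7.35 for LOC107892108, -7.30 for LOC107914060, -7.06 for LOC107958067 and -6.87 for LOC107888194. The highest ranked probe set without a symbol rose by 8.24 (SE 1.19; 7.64, 7.32 and 9.76 without 8 mm anther replicates 1, 6 and 7) and the lowest ranked fell by 10.03. In these 3 comparisons every named call held when any single array of the 2 groups was left out.

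Many calls recurred across bud sizes. At all 3 sizes, 606 probe sets were higher and 1356 lower in anthers. The 5 and 7 mm comparisons shared 867 higher and 1647 lower calls, where independent lists of these lengths would share 231.7 and 314.3. The 7 and 8 mm comparisons shared 1165 higher and 1970 lower calls, against 255.2 and 357.6. The comparisons of different sizes use separate arrays but share the variance estimate of each probe set. Independent lists are therefore not an exact reference. A further 113 probe sets were higher in anthers at some size and lower at another.

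Whether higher or lower calls were more numerous depended on the threshold and on how arrays were scaled. With the adjusted p alone, without the minimum difference, 4964 probe sets were higher and 3047 lower in anthers at 5 mm, 5030 and 3739 at 7 mm, and 4720 and 3264 at 8 mm. With quantile normalization the numbers were 1981 and 2026, 2564 and 2507, and 2279 and 2228. The bioB, bioC and bioD hybridisation spike-ins averaged 9.30 ± 0.28 (SD, n = 3), 9.56 ± 0.43 and 9.92 ± 0.45 in anthers of 5, 7 and 8 mm, against 8.84 ± 0.32, 8.66 ± 0.27 and 8.73 ± 0.28 in the matching buds. Spike-in scaling, as used throughout, shifted each array by its spike-in level and then raised all lower values to a common floor above background. It moved the median difference of all tested probe sets from 0.10, 0.06 and 0.06 to -0.09, -0.49 and -0.77. Its results mix the scaling with that floor. This setting left 505 higher and 2663 lower calls at 5 mm, 504 and 5133 at 7 mm, and 368 and 6420 at 8 mm. Differences of single genes are given relative to the deposited scale.

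**Figure D2:**
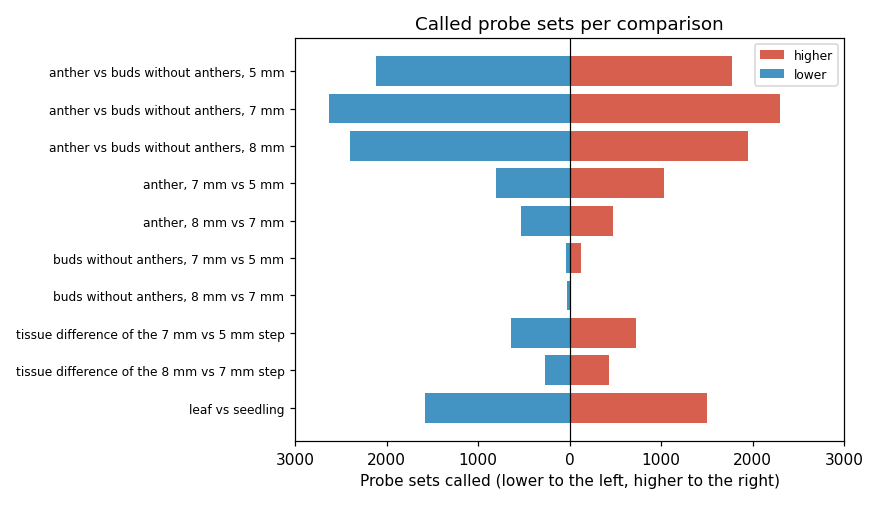
Probe sets called in each of the 10 comparisons, on an axis of counts with higher calls to the right of 0 and lower calls to the left, out of 17666 tested. The 3 comparisons of anthers with buds have the longest bars, from 3887 to 4935 calls, and the bud steps have the shortest, with 170 and 44 calls.

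Transcripts preferential to anthers were defined as higher than in same-size buds, in leaf and in seedling. This held for 827 probe sets at 5 mm, 1155 at 7 mm and 941 at 8 mm, 1968 in all. Of these, 236 belonged to the sets of all 3 sizes, 412 to that of 5 mm alone, 502 to that of 7 mm alone and 335 to that of 8 mm alone. Ranked by the smallest of the 3 differences, the leading locus genes at 5 mm were LOC107956851 with 3.87 (2.58 without 5 mm anther replicate 1 and 4.65 without replicate 4), LOC107961466 with 2.99, LOC107956913 with 2.78 and LOC107925198 with 2.73. At 7 mm they were LOC107956851 with 6.15, LOC107959059 with 4.61, LOC107933034 with 4.16 and LOC107949717 with 3.82. At 8 mm, LOC107930564 exceeded the other tissues at least 16.1-fold, followed by LOC107933034 with 3.86 (3.24 without 8 mm anther replicate 7), LOC107961466 with 3.78 and LOC107956851 with 2.58.

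Few members were at background everywhere else, by a background level that lay only 0.075 above the lowest value. A value above that level on another tissue's array is not thereby shown to be signal. At background on all 15 arrays of other tissues were 18 members of the 5 mm set, 39 of the 7 mm set and 26 of the 8 mm set. The sets of 5 and 7 mm shared 349 members and those of 7 and 8 mm shared 540, against 54.1 and 61.5 for independent lists. The sets use the same leaf and seedling arrays and the same variance estimates, and part of the excess may come from these. Simulated unchanged groups gave sets of 0 members. Those simulations held all 8 groups at the same mean, so they do not give the number of false members where tissues differ. With spike-in scaling the sets held 342, 397 and 261 members, and the 5 mm set held 1252 without 4 arrays that stood apart from their groups, namely 5 mm anther replicate 1, 5 mm bud replicate 2, 7 mm bud replicate 3 and 8 mm bud replicate 6. These 4 were picked on inspection, after the data were seen, and not by a fixed rule. Leaf replicate 4 had 108 probe sets at least 2 log2 units below and 59 above both others of its group, about as many as 8 mm bud replicate 6 with 152 and 10. With it left out too, the sets held 1269, 1174 and 987 members.

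**Figure D3:**
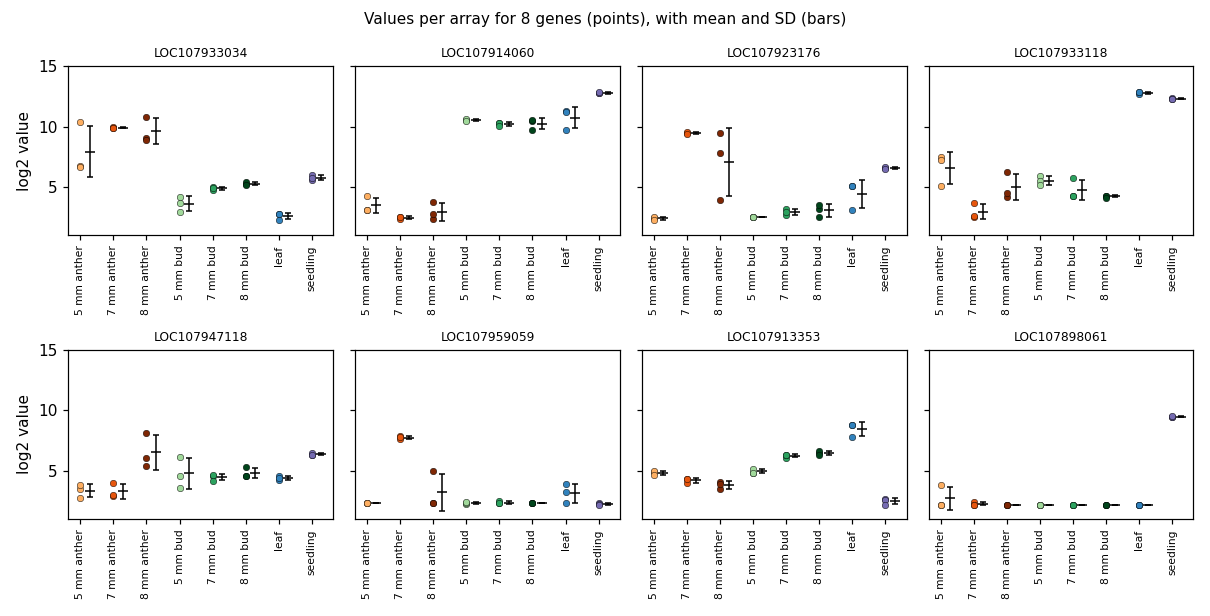
Log2 values of 8 locus genes on each of the 24 arrays (points), with the mean and SD of each group of 3 beside them (bars). LOC107923176 rose from 2.38 in 5 mm anthers to 9.45 in 7 mm anthers, LOC107959059 was high in 7 mm anthers with 7.73, and LOC107898061 was high in seedling with 9.46.

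Within anthers, the step from 5 to 7 mm raised 1036 probe sets and lowered 804. LOC107923176 rose by 7.07 (SE 0.85, adjusted p = 1.13e-05), from 2.38 ± 0.11 (SD, n = 3) to 9.45 ± 0.08. LOC107949717 rose by 6.07 and LOC107959059 by about 5.46, from 2.27 on all 3 arrays of 5 mm anthers, which it also holds on 8 other arrays, so that the size is not exact. LOC107887357 rose by 4.16 and LOC107953630 by 3.43. Falls among locus genes were smaller, with -3.64 for LOC107933118, -3.63 for LOC107928766, and -1.93 each for LOC107928801 and LOC107946937, while LOC107946138, on 1 of its 2 probe sets named here, was at least 5.21-fold lower. Without 5 mm anther replicate 1, the differences were 7.35 for LOC107949717 and -4.40 for LOC107933118, and LOC107946138 was at least 8.58-fold lower. Without 5 mm anther replicate 4, the difference of LOC107949717 was 5.33. LOC107946138 lost its call in a fit of these 6 arrays alone. The highest ranked probe set without a symbol rose by 10.08 (SE 0.40). The count of 1840 became 2937 without the 4 arrays that stood apart, the adjusted p alone gave 2055 higher and 2670 lower calls, and spike-in scaling left 411 and 1181.

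The step from 7 to 8 mm raised 480 probe sets in anthers and lowered 534. LOC107947118 rose by 3.24 (SE 0.59, adjusted p = 0.00125), from 3.28 ± 0.60 (SD, n = 3) to 6.52 ± 1.44. LOC107928766 rose by 3.19, LOC107930564 by 3.04, LOC107908811 by 2.70 and LOC107957278 by 2.32. The largest falls were -4.55 for LOC107959059, -3.56 for LOC107956851, -3.49 for LOC107893293, about -3.45 for LOC107922335, which stood at its lowest value, 3.11, on all 3 arrays of 8 mm anthers, and -3.08 for LOC107909647. LOC107908811 lost its call without 7 mm anther replicate 1, at 2.45, or replicate 2, at 2.72, and stood at 1.31, 3.36 and 3.42 without 8 mm anther replicates 1, 6 and 7. LOC107928766 stood at 2.26 and 4.11 without 8 mm anther replicates 1 and 7, LOC107959059 at -5.45 without replicate 1, LOC107947118 at 2.43 without replicate 7, and LOC107930564 at 3.96 without 7 mm anther replicate 3. In a fit of these 6 arrays alone, LOC107947118, LOC107928766, LOC107930564 and LOC107908811 lost their calls. Higher calls were the more numerous with median centring (532 and 506), with the adjusted p alone (1158 and 1051), at an adjusted p under 0.01 with a difference of at least 2 (117 and 107) and when tested against a difference of 1 (61 and 47). They were so too without 7 mm anther replicate 2 (358 and 334) or 3 (511 and 509) and without 8 mm anther replicate 1 (431 and 403) or 7 (466 and 407). Spike-in scaling left 110 higher and 409 lower calls, and LOC107947118 and LOC107908811 lost theirs.

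Taking both steps, 281 probe sets rose to 7 mm and fell again to 8 mm. Another 70 rose at both steps, 18 fell at both, and 35 fell and then rose. LOC107959059 stood at 7.73 ± 0.14 (SD, n = 3) at 7 mm, 2.27 on all 3 arrays at 5 mm and 3.18 ± 1.56 at 8 mm, a difference of 4.55 from the nearer size that became 5.45 without 8 mm anther replicate 1. LOC107893293, LOC107956851 and LOC107909647 exceeded the nearer size by 2.33, 2.28 and 2.26, which became 3.49, 3.56 and 3.08 without 5 mm anther replicate 1. Each of these 3 left the peak set without 5 mm anther replicate 3 (adjusted p = 0.0954, 0.126 and 0.0596) and without 5 mm anther replicate 4 (1.52, 1.498 and 1.66; adjusted p = 0.114, 0.155 and 0.0803), and in a fit of the 9 anther arrays alone. LOC107893293 left it with the 5′ minus 3′ difference of the poly-A spike-ins as a covariate as well (1.98, adjusted p = 0.0509). LOC107893293 also left it without 7 mm anther replicate 1, at 2.19, and LOC107956851 without 7 mm anther replicate 1 or 2, at 2.06 each. Of the 281 members, 189 were also in the anther-preferential set of 7 mm. The peak set held 478 members without the 4 arrays that stood apart and 145 with spike-in scaling, which left LOC107959059 in it and ended the calls of the other 3 genes named.

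Buds without anthers changed at fewer probe sets. From 5 to 7 mm, 129 rose and 41 fell. Another split of the same 6 arrays, with the sizes mixed, gave 257 calls, more than the real 170. LOC107908968 rose by 4.25 (SE 0.82, adjusted p = 0.0133), from 2.27 ± 0.20 (SD, n = 3) to 6.52 ± 0.24, and LOC107909128 rose by 3.60. LOC107954320 fell by 1.45 and LOC107904848 fell by 1.23. LOC107909128 lost its call without 5 mm bud replicate 2 (3.26) or 4 (3.40) and without 7 mm bud replicate 1 (3.69), 2 (3.73) or 3 (3.37). LOC107904848 lost its call without 5 mm bud replicate 2 (-0.78) and without 7 mm bud replicate 1 (-1.26) or 2 (-1.13), and with array weights (-0.91). Without the 4 arrays that stood apart, LOC107954320 and LOC107904848 lost their calls, at -0.87 and -0.84. With no filter, LOC107909128 (adjusted p = 0.0561) and LOC107904848 (adjusted p = 0.0528) lost theirs. The count of 170 became 403 without 5 mm bud replicate 3, 396 without the 4 arrays that stood apart and 8 in a fit of these 6 arrays alone, where LOC107909128, LOC107954320 and LOC107904848 lost their calls, and spike-in scaling left 55 higher and 2 lower calls, with LOC107908968 alone of the 4 genes kept.

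From 7 to 8 mm, 13 probe sets rose in buds without anthers and 31 fell. LOC107962977 rose by 1.91 and LOC107914052 by 1.77 (SE 0.26, adjusted p = 0.00448), the latter from 6.31 ± 0.27 (SD, n = 3) to 8.08 ± 0.22. No locus gene met the rule for a fall. LOC107962977 lost its call without 7 mm bud replicate 1 or 2, at 1.78 each, and without 8 mm bud replicate 4 (1.92), 5 (1.94) or 6 (1.89), and with no filter (adjusted p = 0.0746). The count of 44 became 28 without 7 mm bud replicate 2, 21 without 8 mm bud replicate 4, 15 without 8 mm bud replicate 5 and 100 without the 4 arrays that stood apart, both genes lost their calls in a fit of these 6 arrays alone, and spike-in scaling left 4 higher and 29 lower calls and ended the calls of both genes.

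The size steps were then compared between anthers and buds. From 5 to 7 mm, 728 probe sets changed more upward in anthers than in buds and 638 more downward. Of these 1366, 586 rose and 371 fell in anthers with no call in buds. Another 311 had no call in either tissue, and 74 rose in buds with no call in anthers. LOC107923176 differed by 6.64 (SE 1.20, adjusted p = 0.0017) and LOC107949717 by 5.80. In the other direction, LOC107909128 differed by -5.33 and LOC107946138, on the other of its 2 probe sets, by -4.47. LOC107949717 lost its call without 5 mm anther replicate 3 (5.26) or 4 (5.05), 5 mm bud replicate 2 (5.27) or 7 mm anther replicate 2 (5.73), and LOC107946138 without 5 mm anther replicate 3 (-4.20) or 4 (-4.24) and in a fit of these 12 arrays alone. Other values that moved were 7.07 for LOC107949717 without 5 mm anther replicate 1 and -6.08 for LOC107909128 without 7 mm anther replicate 3. LOC107946138 stood at -3.86, -5.77 and -3.78 without 5 mm bud replicates 2, 3 and 4. Downward calls were the more numerous without 5 mm anther replicate 1 (1021 and 1108), 5 mm bud replicate 2 (618 and 675), the 4 arrays that stood apart (1066 and 1099), or s_at and x_at probe sets (340 and 409). The count was 2129 without 5 mm anther replicate 1, 885 without 5 mm anther replicate 3 and 2165 without the 4 arrays that stood apart, and spike-in scaling left 130 upward and 540 downward calls, without LOC107949717.

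From 7 to 8 mm, 436 probe sets changed more upward in anthers than in buds and 269 more downward. Of these 705, 286 rose and 218 fell in anthers with no call in buds, and 166 had no call in either tissue. LOC107959059, at its repeated value of 2.27 on all 8 mm bud arrays, differed by about -4.48 (SE 0.68, adjusted p = 0.00101; -5.39 without 8 mm anther replicate 1) and kept its call without each array of the 4 groups in turn and with spike-in scaling, which ended the calls of the next 3 genes. LOC107908811 differed by 3.75, LOC107928766 by 3.13 and LOC107893293 by -3.43. LOC107908811 lost its call without 7 mm anther replicate 1 (3.51) or 2 (3.78), 7 mm bud replicate 1 (3.77) or 3 (3.72), or 8 mm bud replicate 4 (3.84), 5 (3.80) or 6 (3.62), and stood at 2.36, 4.42 and 4.48 without 8 mm anther replicates 1, 6 and 7. LOC107928766 lost it without 7 mm anther replicate 1 (3.03) or 2 (2.87), 7 mm bud replicate 1 (3.19) or 3 (3.00), 8 mm anther replicate 6 (3.13), or 8 mm bud replicate 4 (3.09), 5 (3.27) or 6 (3.02), and stood at 2.20 and 4.05 without 8 mm anther replicates 1 and 7. Both lost their calls in a fit of these 12 arrays alone and without the 4 arrays that stood apart (adjusted p = 0.0747 and 0.0668). LOC107893293 lost it without each array of the 4 groups except 8 mm anther replicate 7, with differences between -3.61 and -3.20, and with quantile normalization (adjusted p = 0.053). With no filter LOC107908811, LOC107928766 and LOC107893293 lost their calls (adjusted p = 0.0629, 0.0585 and 0.0735), as they did with the poly-A covariate (adjusted p = 0.0889, 0.0848 and 0.1). The count was 401 without 7 mm anther replicate 2, 1068 without 7 mm bud replicate 2, 469 without 8 mm bud replicate 5 and 1083 without the 4 arrays that stood apart, spike-in scaling left 37 upward and 56 downward calls, and a test against a difference of 1 left 17 and 18.

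Leaf and seedling differed at 3082 probe sets, of which 1497 were higher and 1585 lower in leaf. LOC107913353 was higher in leaf by 6.00 (SE 0.23, adjusted p = 2.4e-13), with 8.44 ± 0.59 (SD, n = 3) against 2.44 ± 0.24 in seedling, and LOC107916546 was higher by 3.66. LOC107898061 was at background in leaf and at least 150.1-fold lower there than in seedling, and LOC107909128 fell by 6.19, or by 6.80 without leaf replicate 4. The lowest ranked probe set without a symbol stood at 12.98 ± 0.06 (SD, n = 3) in seedling and was at least 1720-fold lower in leaf. Each of these calls held without each leaf or seedling array in turn, and spike-in scaling left 2101 higher and 807 lower calls. Higher calls were also the more numerous with the adjusted p alone (3362 and 3165), array weights (1757 and 1630) or a fit of these 6 arrays alone (1611 and 1553), and without s_at and x_at probe sets (917 and 772) or the 4 arrays that stood apart (1685 and 1645).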

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

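The tests of 7 mm bud replicate 3 and 5 mm bud replicate 2, and the scaling on hybridisation spike-ins, were chosen after the results were seen.

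The step from 5 to 7 mm differed between anthers and buds at 1366 probe sets, and the step from 7 to 8 mm at 705, by a test of the difference between tissues. Among 100 splits of the same arrays with sizes shuffled within each tissue, 8 gave a count as large as 1366, the real split included, and the highest other was 2534, so chance is not excluded at this threshold for the first. All 7 others as large kept the anther arrays in their real size groups, while the highest of the 79 splits that kept neither tissue's groups was 915. For the second, 3 of 100 splits gave a count as large as 705, a share under 0.05, the highest other being 997. Most splits broke up the anther groups and so removed the anther step as well. This share is therefore no test of equal steps in anthers and buds. Both others as large again kept the anther groups, and the highest of the 80 that kept neither was 5. With the anther groups kept and only buds shuffled, 6 of 9 splits for the first and 2 of 7 for the second gave a count as large, so these splits do not show that bud size adds to the counts beyond the anther step.

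A reporter control whose target the labels say was not added, RPTR-Ghi-X03453-2_s_at, averaged 14.2 over the 24 arrays, with a range from 13.9 to 14.5, while the highest value of the other 68 negative controls was 2.78. It stood near the cre hybridisation spike-ins. Both were highest on 8 mm anther replicate 1, at 14.45 for the reporter and 14.13 for cre. The reporter was lowest on 8 mm bud replicate 4, at 13.86, with cre at 13.42. Whether a spiked-in target caused its signal was not tested.

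On 7 mm bud replicate 3, 639 probe sets were at least 2 log2 units below both other 7 mm bud arrays. Its median deviation over all tested probe sets was 0.076, so most tested probe sets were not lower than the mean of the other 2 arrays. Over the whole table, with controls and untested probe sets, its median was 4.96, against 5.25 and 5.23 on the others. The medians of the 24 arrays lay between 7.01 and 7.11 over tested probe sets and between 4.66 and 5.25 over the whole table. The authors had normalized between arrays, so a shift of the whole array before that step cannot be seen here. Its poly-A spike-ins had a 5′ minus 3′ difference of -3.20, the lowest of the 24 arrays, against -1.02 and -0.55 in the other 7 mm buds. On the array with the next lowest difference, 5 mm anther replicate 3 with -2.51, the same probe sets deviated by a median of -0.94, against a lowest of -0.02 in 1000 random lists matched on level. The 2 arrays had been seen to deviate alike beforehand (r = 0.52, the highest of any array of another group), so the low median restates that. Loss of 5′ signal in RNA amplification is a candidate explanation, and no biological explanation was tested, since the labels give none within a group.

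On 5 mm bud replicate 2, 543 probe sets were at least 2 log2 units below both other 5 mm bud arrays. Its poly-A difference lay -0.12 from the mean of the others, which argues against loss of 5′ signal in RNA amplification. Anther tissue left in the sample would have to supply 75% of the RNA, yet 19 probe sets abundant in anthers stood at a median of -4.91 relative to their anther level, and at -3.67 on the other arrays. On 8 mm bud replicate 6 the same 543 probe sets deviated by a median of -0.82, but that array was picked because its deviations had the highest correlation with those of this one (r = 0.56), so the value restates that choice. A bud part under-represented in the sample stays open, and no biological explanation was tested.

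Falls of at least 8-fold outnumbered rises in 7 mm anthers against buds, 712 to 223, a share of 76.2%. With scaling on the hybridisation spike-ins the share was 92.7%, but these stood 0.909 higher in the anthers, so that scaling on them shifts anther values downward whatever the cause of the pattern. Among probe sets above background on all 6 arrays it was 76.3%, but background lay 0.075 above the lowest value, so this filter keeps values compressed near it. Between-array scaling, compression at the lower limit and a biological difference between the tissues all stay open.

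For comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The counts, each followed by the highest other split, were 3887 and 790 for anthers against buds at 5 mm, 4935 and 2 at 7 mm, and 4358 and 5 at 8 mm. They were 1840 and 57 for the anther step to 7 mm, 1014 and 11 for the anther step to 8 mm, 170 and 257 for the bud step to 7 mm, 44 and 9 for the bud step to 8 mm, and 3082 and 34 for leaf against seedling. In each case 1 split, the real one, gave a count as large, except that 2 did for the bud step to 7 mm.

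Among 100 splits, the share as large, the real split included, was under 0.05 for each set. The 5 mm anther-preferential set held 827 members (highest other 573, 1 as large). That of 7 mm held 1155 (highest other 1470, 2 as large) and that of 8 mm 941 (highest other 1174, 2 as large). The peak set held 281 (highest other 600, 3 as large). The other splits as large had a whole real group in the tested place: 7 mm anthers for the 7 mm set, 8 mm anthers for the 8 mm set, and 5 mm or 8 mm anthers for the peak set. With a mixture of groups in that place the highest counts were 19, 23, 26 and 49. All but a few splits were such mixtures, so the small shares show only that the groups are not interchangeable.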

How the results depend on the processing

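Spike-in scaling, the exclusion of 4 or 5 arrays and the poly-A covariate were chosen after seeing the data. Of 355 recomputed counts, 258 stayed within 1.5 times the reported count. Of 3176 recomputed values of single probe sets, 2928 kept their direction and call, 248 lost the call and 0 reversed. No count moved by over 1.5 times with no filter, the stricter filter, the floor, quantile normalization, median centring or the trended robust prior. Of 131 calls of single probe sets, however, 9 were lost with no filter and 1 with quantile normalization, and 27 in fits of the compared groups alone, 21 with spike-in scaling, 6 with the poly-A covariate, 5 without 4 arrays, 5 without 5, 1 with array weights, 26 at stricter thresholds and 38 when tested against a difference of 1. The block is given below. Where a setting moved a count or ended a call the cause was not tested, except that thresholds and probe set types change the number by construction. The 4 arrays left out together were picked because they stood apart from their groups, so a smaller spread without them was to be expected. Higher counts without them are therefore no evidence of more changes. The gene list alternatives were not run, since no list had a member. Values near the lower limit of GCRMA limit what differences can be seen.

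With the adjusted p alone, the counts were 8011 for anthers against buds at 5 mm, 8769 for anthers against buds at 7 mm, 7984 for anthers against buds at 8 mm, 4725 for the anther step to 7 mm, 2209 for the anther step to 8 mm, 374 for the bud step to 7 mm, 6527 for leaf against seedling, 3105 for the 5 mm set, 3004 for the 7 mm set, 2677 for the 8 mm set and 583 for the peak set. At an adjusted p under 0.01 and a log2 difference of at least 2, they were 1211 for anthers against buds at 5 mm, 1921 for anthers against buds at 7 mm, 1754 for anthers against buds at 8 mm, 397 for the anther step to 7 mm, 224 for the anther step to 8 mm, 17 for the bud step to 7 mm, 6 for the bud step to 8 mm, 303 for the tissue difference to 7 mm, 125 for the tissue difference to 8 mm, 1006 for leaf against seedling, 127 for the 5 mm set, 322 for the 7 mm set, 264 for the 8 mm set and 53 for the peak set. Tested against a difference of 1, they were 1239 for anthers against buds at 5 mm, 2113 for anthers against buds at 7 mm, 1968 for anthers against buds at 8 mm, 286 for the anther step to 7 mm, 108 for the anther step to 8 mm, 2 for the bud step to 7 mm, 1 for the bud step to 8 mm, 128 for the tissue difference to 7 mm, 35 for the tissue difference to 8 mm, 1045 for leaf against seedling, 164 for the 5 mm set, 425 for the 7 mm set, 354 for the 8 mm set and 27 for the peak set. Without s_at and x_at probe sets, they were 2223 for anthers against buds at 5 mm, 2682 for anthers against buds at 7 mm, 2400 for anthers against buds at 8 mm, 988 for the anther step to 7 mm, 533 for the anther step to 8 mm, 105 for the bud step to 7 mm, 749 for the tissue difference to 7 mm, 378 for the tissue difference to 8 mm, 1689 for leaf against seedling, 505 for the 5 mm set, 599 for the 7 mm set, 514 for the 8 mm set and 149 for the peak set. In fits of the compared groups alone, they were 8 for the bud step to 7 mm, 20 for the bud step to 8 mm, 598 for the tissue difference to 7 mm and 140 for the peak set. With array weights, they were 376 for the bud step to 7 mm, 132 for the bud step to 8 mm, 1213 for the tissue difference to 8 mm and 453 for the peak set. With spike-in scaling, they were 6788 for anthers against buds at 8 mm, 519 for the anther step to 8 mm, 57 for the bud step to 7 mm, 670 for the tissue difference to 7 mm, 93 for the tissue difference to 8 mm, 342 for the 5 mm set, 397 for the 7 mm set, 261 for the 8 mm set and 145 for the peak set. Without 5 mm anther replicate 1, 5 mm bud replicate 2, 7 mm bud replicate 3 and 8 mm bud replicate 6, they were 2937 for the anther step to 7 mm, 396 for the bud step to 7 mm, 100 for the bud step to 8 mm, 2165 for the tissue difference to 7 mm, 1083 for the tissue difference to 8 mm, 1252 for the 5 mm set and 478 for the peak set. With leaf replicate 4 left out as well, they were 2970 for the anther step to 7 mm, 446 for the bud step to 7 mm, 128 for the bud step to 8 mm, 2261 for the tissue difference to 7 mm, 1185 for the tissue difference to 8 mm, 1269 for the 5 mm set and 481 for the peak set. With the poly-A covariate, the count was 267 for the bud step to 7 mm.

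Spike-in scaling moved the median of all tested probe sets by over 0.1 log2 also in the anther steps, to -0.14 and -0.18, in the tissue difference to 7 mm, to -0.31, and in leaf against seedling, to 0.16.

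With each array of the compared groups left out in turn, the counts ranged from 3495 to 4388 for anthers against buds at 5 mm, 4592 to 5169 for anthers against buds at 7 mm, 3943 to 4551 for anthers against buds at 8 mm, 1319 to 2588 for the anther step to 7 mm, 692 to 1098 for the anther step to 8 mm, 149 to 403 for the bud step to 7 mm, 15 to 46 for the bud step to 8 mm, 885 to 2129 for the tissue difference to 7 mm, 401 to 1068 for the tissue difference to 8 mm, 2909 to 3039 for leaf against seedling, 748 to 1118 for the 5 mm set, 1090 to 1178 for the 7 mm set, 885 to 975 for the 8 mm set, 188 to 349 for the peak set.

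The labels do not say what the replicate numbers share. The correlations of deviations of same-numbered arrays, across probe sets, were -0.03, 0.12 and -0.13 in 7 mm anthers and buds, and 0.05, -0.10 and -0.05 in 5 mm buds and leaf, the pairs of groups that share 3 numbers. Of pairs that share 2, 5 mm anthers and 7 mm buds had 0.28 and 0.52, and 5 mm buds and 7 mm anthers 0.23 and 0.26. Each other pair of groups had a value under 0.1, and 1 number is shared by the 8 mm groups. The numbers were not taken to pair the samples. With the replicate number as a block, the counts were 3952 for anthers against buds at 5 mm, 4846 for anthers against buds at 7 mm, 4063 for anthers against buds at 8 mm, 1558 for the anther step to 7 mm, 680 for the anther step to 8 mm, 83 for the bud step to 7 mm, 1 for the bud step to 8 mm, 1145 for the tissue difference to 7 mm, 453 for the tissue difference to 8 mm, 2428 for leaf against seedling, 781 for the 5 mm set, 1044 for the 7 mm set, 870 for the 8 mm set, 159 for the peak set. Of 131 calls of single probe sets, 15 were lost with it, among them LOC107947118 and LOC107922335 in the anther step to 8 mm, LOC107962977 and LOC107914052 in the bud step to 8 mm, LOC107949717 in the 7 mm set and LOC107916546 in leaf against seedling.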

Other observations

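The comparisons of single arrays and of probe set names were chosen after the values were seen. On 7 mm anther replicate 3, 77 probe sets were at least 2 log2 units above both other 7 mm anther arrays. Of these, 46 (59.7%) were also at least 1 higher in 8 mm anthers than in those 2 arrays, against a median of 5.19% in 1000 random lists matched on the level of those 2 arrays. The probe set ranked highest for the anther step from 7 to 8 mm, which has no gene symbol, stood at 13.18 on that array, at 3.42 and 3.35 on the other 7 mm anther arrays, and at 13.76 to 14.31 in 8 mm anthers. Its difference of 7.41 was 5.80, 5.76 and 10.68 without 7 mm anther replicates 1, 2 and 3, and its call was lost in a fit of these 6 arrays alone. In buds without anthers it stood at 8.13 ± 0.28 (SD, n = 3) at 8 mm and 2.76 ± 0.42 at 7 mm.

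On 5 mm anther replicate 1, 174 probe sets stood at least 2 log2 units above both others of its group, of which 149 (85.6%) were also at least 1 higher than those 2 in 7 mm anthers and 116 (66.7%) in 5 mm buds. Random lists matched in the same way had medians of 12.1% and 21.8%. Choosing probe sets that are low on 2 arrays favours higher values elsewhere, which this matching does not remove, so the shares for both arrays are no test. On leaf replicate 4, 108 probe sets were as far below the other leaf arrays and 59 as far above.

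Of 14307 tested probe sets with names starting Ghi or GhiAffx, 11.8% were anther-preferential at some size, against 8.17% of 3254 with names starting Gra or GraAffx (two-sided Fisher's exact test across probe sets, which are not independent, p = 1.08e-09). Called lower in anthers at some size were 20.6% of Ghi, 21.7% of GhiAffx, 13.9% of Gra and 11.1% of GraAffx names, so the lower share of the last 2 was not particular to anther preference.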
